A study of Homo sapiens with 8 samples.

How the data were processed

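RNA was measured by sequencing of poly(A)-selected, stranded libraries from the iPS(IMR90)-4 line on days 0, 1, 3 and 5 of differentiation, with 2 libraries per day and 8 in all. Per the labels, the authors trimmed reads with Trimmomatic and aligned them with STAR to GRCh38, and no versions of these tools are given in the sources used here, nor the abundance estimator or the annotation. The deposited table holds 1 column of TPM per library, made by the authors, and replicates were not pooled. Each column summed to between 999714 and 999989, so the values are fractions of a library and not read counts. Depth is not kept by this unit, and the precision that depth gives cannot be stated. The p-values measure the spread among these samples of 1 line. All columns of the table belonged to a sample.

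The table had 31166 rows. Rows that shared a gene identifier (37 repeats of 36 identifiers) were summed, which left 31129 genes. Symbols were taken by Ensembl identifier from a name table (30701 genes matched), which also restored 27 symbols that the file shows as dates, and positions were taken from GENCODE release 29 on GRCh38 (30983 genes matched). None of 14 housekeeping genes was at 0 in any library. In each library 335 to 378 rows lay between 0 and 0.001 TPM, and these values were kept as they are.

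Samples were grouped by day. The comparisons, tests, gene lists and alternatives were chosen before the data were examined. Genes with at least 1 TPM in at least 2 of the 8 libraries were tested (16888 genes). Values were transformed as log2(TPM + 1) and fitted in limma 3.58.1 (R 4.3.3) with 1 mean per day over all 8 libraries, which leaves 4 residual degrees of freedom, followed by empirical Bayes moderation with a trend in the mean. Each later day was compared with day 0, day 3 with day 1 and day 5 with day 3, two-sided, and limma's F test asked for a difference among the days. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p below 0.05. The comparisons against day 0 share their day 0 libraries, so overlaps and correlations between them were not computed, and differences between later days rest on direct contrasts.

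The 38 gene lists covered pluripotency (core, naive and primed), trophoblast (trophectoderm, cytotrophoblast, syncytiotrophoblast and extravillous trophoblast), amnion, other cell types that such cultures could hold, cell structure, signalling responses, HOX genes, cell cycle, metabolism, stress, immune, imprinted, mitochondrially encoded and ribosomal protein genes. Of 562 members, 550 were in the table, and the other members are not analysed here. In some lists many members in the table stayed under the expression filter. Tested were 7 of 22 for syncytiotrophoblast, 8 of 14 for extravillous trophoblast and 8 of 23 for HOX paralogs 5 to 13. For neural progenitor genes 6 of 14 were tested, and for primitive streak genes 5 of 10. Each list was tested against the other genes with camera in limma at a preset correlation of 0.01 between genes, over 114 tests (38 lists and the 3 comparisons against day 0) adjusted together, and again with an estimated correlation. With the estimated correlation, the estimate and the reference distribution of the test both rest on 4 residual degrees of freedom. A list could therefore hardly pass over 114 tests, and none did in any comparison. This failure leaves open whether correlation between genes accounts for the calls. Each list call is given with both p-values. Counts of called members are given over all genes tested and adjusted over the list alone. Some genes belong to programmes of several tissues, so a list names its source and not a cell type found.

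The genes named in the text follow a rule: for each comparison the 5 largest rises and the 5 largest falls among called genes with no overlap between days and at least 10 TPM in the higher day, up to 4 called members of each list with the largest differences, members that did not pass or went against their list, and, against day 0, 27 key genes. Genes without a symbol were counted and not named. Genes named outside this rule are marked as such, and alternatives were run for all of these genes.

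The model was tested on simulated data before use, with the residual spread of 16888 genes and 200 changed genes. For day 5 against day 0, it called 4%, 60%, 92% and 98% of genes changed by 0.5, 1, 2 and 4 on the log2 scale, with 3 false calls among 16688 unchanged genes. The changed genes were drawn from the better expressed ones, so these rates do not cover genes near the filter. With no list shifted camera called 0 of 114 list tests, and with 1 list shifted by 1 it called that list. The simulated genes varied independently of each other, so this does not test false list calls that correlated genes could bring.

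Alternatives changed 1 choice at a time: a pseudocount of 0.1 TPM, no filter, a minimum of 5 TPM, median-ratio scaling between libraries, no trend in the prior variance, only the 4 libraries of the 2 days compared, a replicate block, each library left out in turn, and the estimated correlation for lists. Leaving out short non-coding genes (235 genes), or mitochondrial and ribosomal protein genes (93 genes), was chosen after seeing the data. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.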

Results

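The data cover 8 RNA sequencing libraries from 1 established human induced pluripotent stem cell line, iPS(IMR90)-4, sampled on days 0, 1, 3 and 5 of culture toward trophectoderm, the outer layer of the blastocyst that gives rise to the trophoblast of the placenta. Each day has 2 libraries, labelled as biological replicates. Cells were kept in a medium based on knockout serum replacement with 1 µM retinoic acid, which activates nuclear retinoic acid receptors, and 8 µM CHIR99021, an inhibitor of GSK3 that activates WNT signalling. The labels do not say outright that day 0 was collected before the change to this medium, so differences from day 0 are differences between days and not stated effects of the medium. The series asks how transcript levels change over these days, so each later day was compared with day 0 and each step with the day before it. Values are TPM, a share of all transcripts in a library, written as the mean and the SD of the 2 libraries of a day. TPM keeps no read counts, so the depth of each library is unknown and no interval or detection floor that needs it can be given. Differences are on the log2(TPM + 1) scale, which understates changes of genes near or below 1 TPM. For each gene list, the text gives how many tested members rose, fell or did not pass when adjusted over all genes, followed by the rises and falls when adjusted over the list alone. The list as a whole was tested with camera in limma. Its adjusted p is given first at a preset correlation of 0.01 between genes, which gave 47 calls in 114 tests. For called lists the adjusted p at an estimated correlation follows, which gave 0 calls. That second test rests on 4 residual degrees of freedom and has little power. Its 0 calls thus leave open whether correlation between genes accounts for the 47.

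The columns summed to between 999714 and 999989 TPM, and 14630 to 15384 genes reached 1 TPM in a library. The first principal component held 62.8% of the variance and separated days 0 and 1 from day 3 and day 3 from day 5. The second held 18.5%, and day 3 lay at its far end. Replicates of a day correlated across genes with Pearson r of 0.988 on day 0, 0.988 on day 1, 0.979 on day 3 and 0.979 on day 5, against 0.831 to 0.845 between day 0 and day 5 libraries (genes are not independent replicates). Mitochondrially encoded mRNA took 11.4% and 11.2% of TPM on day 0, 9.75% and 11.1% on day 1, 9.77% and 8.42% on day 3, and 6.32% and 12.1% on day 5 in replicates 1 and 2. Ribosomal protein genes took 13.8% and 13.9% on day 0, 14.97% and 14.99% on day 1, 19.1% and 12.9% on day 3, and 22.9% and 20.5% on day 5. Relative to day 0, the median of all tested genes moved by 0.11 on day 3, and from day 1 to day 3 it moved by 0.15, so changes that include day 3 stand on that shift. It rests on 1 library: without day 3 replicate 1 these medians were 0.24 and 0.28, without day 3 replicate 2 they were -0.00330 and 0.0254, and replicate 1 lay below replicate 2 by a median of 0.28.

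**Figure D1:**
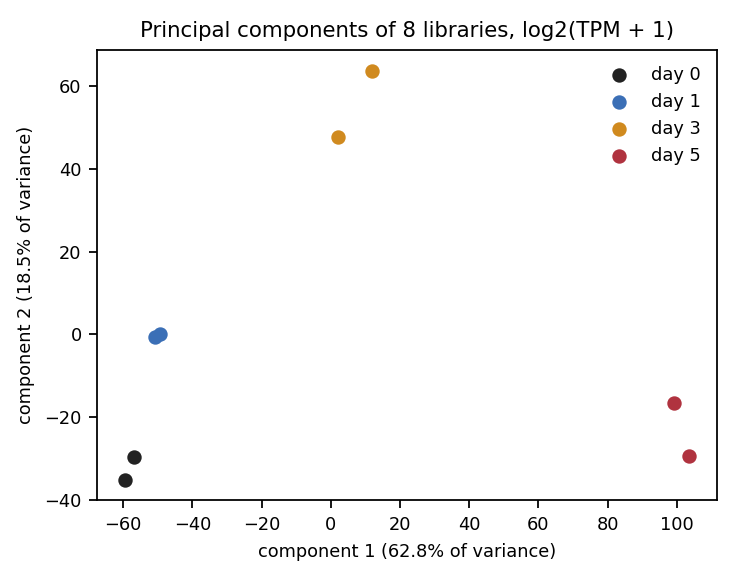
Each point is 1 of the 8 libraries, coloured by day, on principal component 1 (62.8% of the variance) and principal component 2 (18.5%) of log2(TPM + 1) over 16888 genes. On these 2 components each library lies closest to the other library of its day, days 0 and 1 share the left side, and day 5 lies at the right.

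Between day 0 and day 1, genes that answer to retinoic acid (7 of 11 tested) and WNT (7 of 14) rose, and genes of cholesterol synthesis (17 of 20) fell. RARB, a retinoic acid receptor gene, rose from 0.965 TPM ± 0.647 (SD, n = 2) to 23.6 TPM ± 1.11 (SD, n = 2). HMGCS1, an enzyme early in cholesterol synthesis, fell from 795 TPM ± 139 (SD, n = 2) to 114 TPM ± 23.5 (SD, n = 2). The pluripotency factor POU5F1 stood at 2385 TPM ± 24.6 (SD, n = 2) on day 0 and 2148 TPM ± 30.3 (SD, n = 2) on day 1, a difference that did not pass the test (limma adjusted p = 0.677). NANOG (50.8 ± 1.78 and 45.4 ± 2.89 TPM) and SOX2 (111 ± 1.84 and 76.6 ± 2.91 TPM) did not pass either.

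In the retinoic acid response list on day 1, 7 of 11 rose, 0 fell and 4 did not pass (8 and 0 over the list alone), with camera adjusted p = 4.68e-11, or 0.438 with an estimated correlation. CYP26A1, the enzyme that degrades retinoic acid, rose to 640.0 ± 32.7 TPM by 5.27 (SE 0.86, limma adjusted p = 0.00771). The binding protein genes CRABP2 (from 83.8 ± 35.7 to 618 ± 80.9 TPM) and RBP1 (from 33.1 ± 10.4 to 259.6 ± 59.5 TPM) rose with RARB. Among HOX genes of paralog groups 1 to 4, which pattern the anterior body axis, 3 of 12 rose, 0 fell and 9 did not pass (3 and 0 over the list alone), with camera adjusted p = 8.58e-04, or 0.475 with an estimated correlation. HOXA1 rose to 168 ± 22.8 TPM from 13.2 TPM in replicate 1 and 0 in replicate 2 of day 0 (limma adjusted p = 0.00763). HOXB1 reached 15.8 ± 5.50 TPM and HOXB2 10.3 ± 1.54 TPM, from 0.597 ± 0.708 and 0.211 ± 0.218 TPM. No member of the HOX paralogs 5 to 13 list passed on day 1. HOTAIRM1, an antisense RNA beside HOXA1, rose from 16.9 and 0.0839 TPM in the day 0 libraries to 272 ± 60.1 TPM, and reads of overlapping genes make its level uncertain. In day 0, CYP26A1 stood at 56.7 TPM in replicate 1 and 3.76 in replicate 2, and CDX1 at 2.85 and 0 TPM. The calls of HOXA1, HOTAIRM1 and CYP26A1 ended without day 1 replicate 2 (limma adjusted p = 0.0570, 0.0617 and 0.0519), and that of CYP26A1 also without day 1 replicate 1 (0.0512). They also ended with no filter (0.0975, 0.102 and 0.0985) and with only the 2 days compared (0.0706, 0.0678 and 0.0674).

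For the WNT response list, 7 of 14 rose, 0 fell and 7 did not pass (7 and 0 over the list alone), with camera adjusted p = 7.50e-06, or 0.455 with an estimated correlation. CDX1, a homeobox gene induced by WNT and retinoic acid, rose to 61.0 ± 34.6 TPM by a log2 difference of 4.86 (limma adjusted p = 0.00157). The WNT target SP5 rose from 0.434 ± 0.613 to 20.6 ± 14.1 TPM, and TCF7, a transcription factor of the pathway, from 8.34 ± 3.11 to 65.6 ± 9.48 TPM. AXIN2, a feedback inhibitor of WNT, rose from 12.8 ± 0.732 to 40.0 ± 9.50 TPM (limma adjusted p = 0.00467), but not without day 0 replicate 2 (adjusted p = 0.0558) or day 1 replicate 2 (0.0587). In the NODAL pathway list, 4 of 7 rose, 0 fell and 3 did not pass (4 and 2 over the list alone), with camera adjusted p = 0.00557, or 0.438 with an estimated correlation. That call ended with only the 2 days compared (0.0726). The NODAL antagonists LEFTY2 (from 22.9 ± 17.5 to 361 ± 16.3 TPM) and LEFTY1 (from 76.0 ± 7.08 to 301 ± 36.8 TPM) and NODAL itself (from 54.0 ± 4.05 to 188 ± 32.9 TPM) rose. Primitive streak genes gave 1 rise and 0 falls among 5 members, and 4 did not pass (3 and 0 over the list alone), with camera adjusted p = 0.00160, or 0.438 with an estimated correlation. EOMES, a T-box factor of the streak, rose from 0.297 ± 0.173 to 4.91 ± 1.19 TPM, and TBXT stayed under the expression filter (0.110 and 1.33 TPM on day 1). For the BMP response list, 4 of 11 rose, 1 fell and 6 did not pass (5 and 1 over the list alone), with camera adjusted p = 0.0147, or 0.581 with an estimated correlation, a call that ended with only the 2 days compared (0.111).

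Cholesterol synthesis had the smallest list p on day 1: 0 of 20 rose, 17 fell and 3 did not pass (0 and 19 over the list alone), with camera adjusted p = 1.07e-25, or 0.438 with an estimated correlation. HMGCS1 fell by 2.79 (SE 0.22, limma adjusted p = 4.39e-04). MVD, of the mevalonate pathway, fell from 219.8 ± 1.25 to 45.3 ± 0.261 TPM, and LSS, which forms lanosterol, from 124 ± 3.59 to 27.7 ± 2.73 TPM. INSIG1, a sterol-regulated retention protein, fell from 110.1 ± 6.39 to 30.7 ± 4.45 TPM. SC5D (190.5 ± 2.29 and 141 ± 11.6 TPM), SREBF2 (150.0 ± 7.01 and 82.4 ± 5.28 TPM) and STARD4 (69.4 ± 8.81 and 36.0 ± 8.86 TPM) did not pass. ACSS2, which makes acetyl-CoA from acetate, fell by 2.68 and SPIB, an ETS transcription factor, by 2.67. HCN1, a channel of pacemaker currents, fell from 376 ± 88.2 to 4.67 ± 5.01 TPM (limma adjusted p = 0.00845). The HCN1 call ended without day 0 replicate 1 (0.0613), day 0 replicate 2 (0.0563) or day 1 replicate 2 (0.0714), and with no filter (0.103).

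Among p53 targets on day 1, 8 of 15 rose, 1 fell and 6 did not pass (10 and 1 over the list alone), with camera adjusted p = 1.26e-06, or 0.469 with an estimated correlation. GDF15, a secreted stress response factor, rose from 5.97 ± 2.24 to 38.1 ± 4.19 TPM and PHLDA3, an inhibitor of AKT, from 23.5 ± 3.602 to 79.7 ± 10.1 TPM. Core pluripotency genes gave 0 rises and 4 falls among 20 members, and 16 did not pass (0 and 6 over the list alone), with camera adjusted p = 6.80e-05, or 0.475 with an estimated correlation. Of the primed pluripotency genes, 1 of 12 rose, 6 fell and 5 did not pass (2 and 9 over the list alone), with camera adjusted p = 2.99e-04, or 0.475 with an estimated correlation. OTX2, a homeobox gene of the epiblast, fell from 38.4 ± 0.928 to 7.29 ± 1.22 TPM. Trophectoderm genes gave 3 rises and 0 falls among 19 members, and 16 did not pass (4 and 0 over the list alone), with camera adjusted p = 0.00232, or 0.495 with an estimated correlation. CDX2, a homeobox gene of the trophectoderm, rose from 0.556 ± 0.684 to 9.64 ± 5.08 TPM by 2.76 (limma adjusted p = 0.00357, or 0.0564 with no filter). In the mesenchymal list, 3 of 11 rose, 0 fell and 8 did not pass (4 and 0 over the list alone), with camera adjusted p = 9.63e-04, or 0.438 with an estimated correlation. The collagen genes COL1A2 (from 23.5 ± 4.13 to 96.9 ± 0.506 TPM) and COL1A1 (from 87.8 ± 9.67 to 321 ± 15.8 TPM) rose. For antigen presentation and interferon genes, 3 of 15 rose, 0 fell and 12 did not pass (7 and 0 over the list alone), with camera adjusted p = 3.47e-04, or 0.455 with an estimated correlation. Syncytiotrophoblast genes gave 2 rises and 0 falls among 7 members, and 5 did not pass (3 and 1 over the list alone), with camera adjusted p = 0.0347, or 0.495 with an estimated correlation. That list call ended with median-ratio scaling (0.0554) and without day 0 replicate 2 (0.112), day 1 replicate 1 (0.0592), day 3 replicate 1 (0.0504) or day 5 replicate 1 (0.0517). It also ended with no filter (0.101), a minimum of 5 TPM (0.319), only the 2 days compared (0.111) and mitochondrial and ribosomal protein genes left out (0.216). DNA replication genes gave 0 rises and 0 falls among 14 members, and 14 did not pass (0 and 0 over the list alone), with camera adjusted p = 0.0308, or 0.701 with an estimated correlation. Its call ended with median-ratio scaling (0.0608), with no trend (0.0568) and without day 0 replicate 1 (0.0914), day 1 replicate 1 (0.0512) or day 1 replicate 2 (0.0593). The median, the mean and the direction of the camera test differed in sign on day 1 for the naive pluripotency, extravillous trophoblast, amnion, neuron, basement membrane, FGF and ERK response, and imprinted lists, none of which passed.

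Over all 16888 genes tested, 1018 changed between day 0 and day 1 in limma (Benjamini-Hochberg adjusted p below 0.05), 581 higher and 437 lower, and 661 of them by at least 1 on the log2 scale. The count was 337 without day 0 replicate 1, 241 without day 0 replicate 2, 316 without day 1 replicate 1 and 262 without day 1 replicate 2, where the remaining library of that day is assumed to vary like the other days, and 1807 and 1810 without day 3 replicates 1 and 2. Of 75 called results of named genes and list members in this comparison, 44 ended when some library was left out. TMSB4XP8, a processed pseudogene of TMSB4X, was listed at 0 TPM in both day 0 libraries and at 85.3 ± 13.01 TPM on day 1, and reads it shares with its parent gene make that level uncertain. It and a like pseudogene, TMSB4XP6, both stood at 76.117 TPM in day 1 replicate 1, and at 94.519 and 189.04 TPM in replicate 2. Very few reads on a short gene would give such steps, so the rise may rest on very few reads. In GRCh38 coordinates of GENCODE release 29, HOXA1 lies on chromosome 7 from 27092993 to 27095996 on the minus strand, CYP26A1 on chromosome 10 from 93073475 to 93077890 on the plus strand, CDX1 on chromosome 5 from 150166795 to 150184558 on the plus strand, HMGCS1 on chromosome 5 from 43289395 to 43313512 on the minus strand and HCN1 on chromosome 5 from 45254950 to 45696498 on the minus strand.

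**Figure D2:**
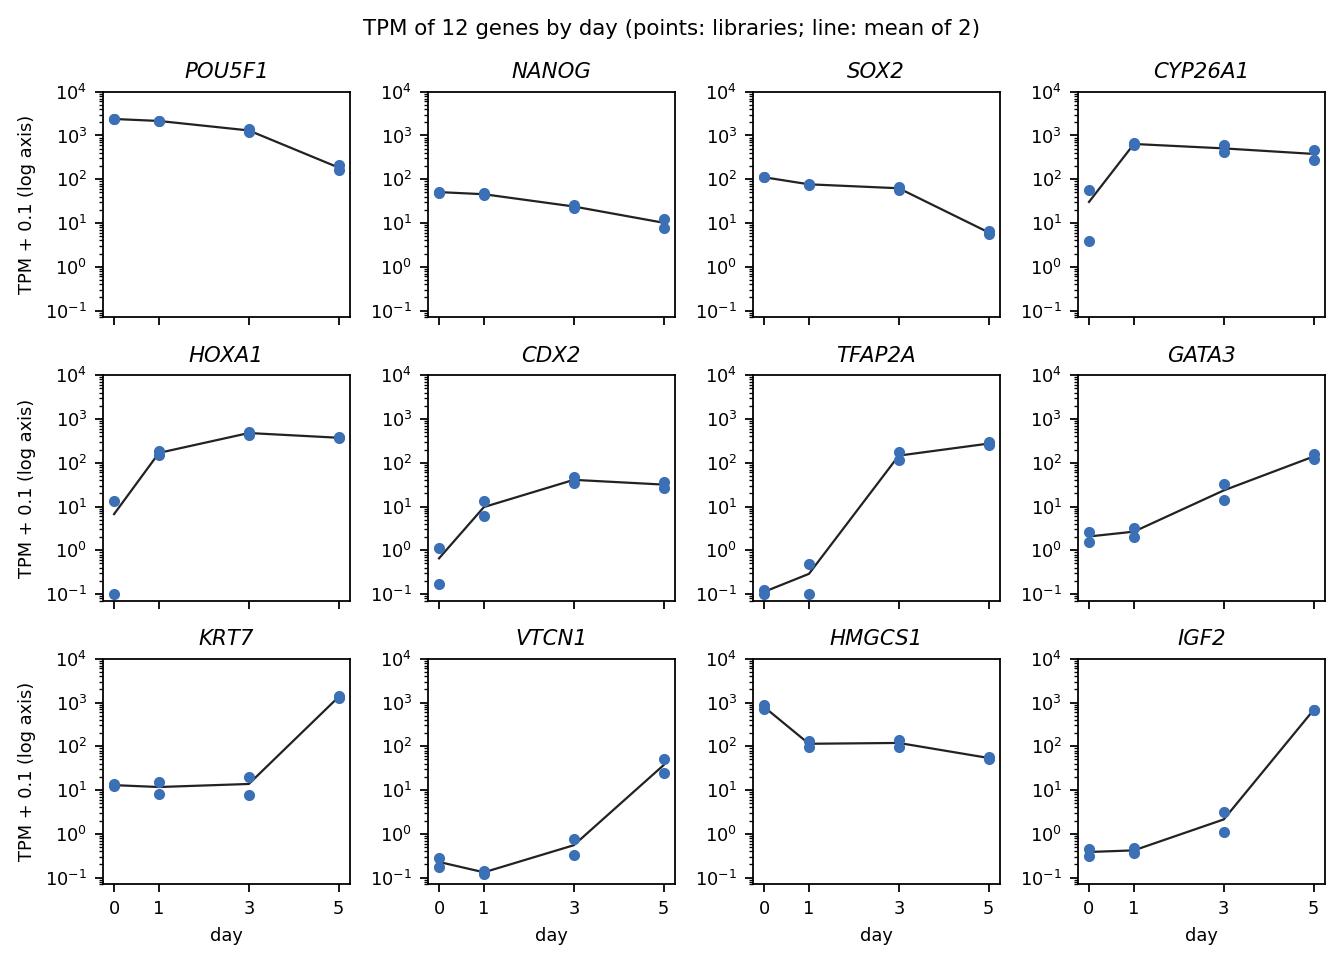
TPM plus 0.1 of 12 genes on a log axis against day, where each point is a library and each line joins the means of 2 libraries. CYP26A1 and HOXA1 stood apart between the day 0 replicates (56.7 and 3.76 TPM for CYP26A1), HMGCS1 was lower from day 1, and KRT7 and IGF2 were higher on day 5 than on day 3.

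By day 3, TFAP2A and GATA3 were higher, and 14 of 15 p53 targets and 8 of 11 BMP response genes had risen. TFAP2A, an AP-2 factor of trophectoderm and surface ectoderm, rose from 0.0123 TPM ± 0.0174 (SD, n = 2) to 146 TPM ± 39.5 (SD, n = 2). GATA3, a trophectoderm factor, rose from 1.97 TPM ± 0.717 (SD, n = 2) to 23.3 TPM ± 12.9 (SD, n = 2). POU5F1 fell from 2385 ± 24.6 to 1304 TPM ± 122 (SD, n = 2), a log2 difference of -0.87 (limma adjusted p = 0.00339). MYC, a growth-promoting transcription factor, fell from 102 ± 1.19 to 1.34 TPM ± 0.547 (SD, n = 2).

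In the trophectoderm list on day 3, 10 of 19 rose, 2 fell and 7 did not pass (12 and 3 over the list alone), with camera adjusted p = 6.92e-04, or 0.475 with an estimated correlation. TFAP2A rose by 7.15 (SE 0.24, limma adjusted p = 9.41e-07). CDX2 reached 40.6 ± 9.08 TPM, the epithelial factor ELF3 109 ± 35.1 TPM, and TFAP2C 93.2 ± 26.0 TPM, from 0.556 ± 0.684, 6.89 ± 1.31 and 6.65 ± 1.06 TPM. GATA2 reached 14.1 ± 5.28 TPM, and HAND1, a basic helix-loop-helix factor of trophoblast and mesoderm, was listed at 0 TPM in both libraries of day 0 and at 5.19 ± 0.721 TPM on day 3. TEAD4, a factor of mouse trophectoderm, fell from 94.8 ± 1.79 to 30.7 ± 0.687 TPM. The keratins KRT7 (12.8 ± 1.17 and 13.7 ± 8.80 TPM) and KRT8 (297 ± 7.46 and 382 ± 25.2 TPM) did not pass. KRT18 fell from 502 ± 17.9 to 339 ± 35.9 TPM (limma adjusted p = 0.0250), but not with no filter (0.0785) or no trend (0.0516), or without day 0 replicate 1 (0.108) or 2 (0.157), day 1 replicate 1 (0.0535) or 2 (0.0533), or day 3 replicate 1 (0.0644). Surface ectoderm and epidermis genes gave 3 rises and 2 falls among 8 members, and 3 did not pass (3 and 2 over the list alone), with camera adjusted p = 0.118. DLX5, a homeobox gene, rose from 0.0441 ± 0.0624 to 114 ± 33.9 TPM, GRHL3, a factor of epidermal differentiation, from 0.737 ± 0.0117 to 119.7 ± 47.1 TPM, and DLX3 from 0.259 ± 0.0266 to 11.6 ± 4.69 TPM. For the amnion list, 5 of 11 rose, 0 fell and 6 did not pass (5 and 0 over the list alone), with camera adjusted p = 0.0306, or 0.528 with an estimated correlation. That call ended without day 3 replicate 1 (0.0635). Cytotrophoblast genes gave 2 rises and 0 falls among 11 members, and 9 did not pass (2 and 0 over the list alone), with camera adjusted p = 0.704. CDH1, the epithelial cadherin, rose from 127 ± 0.259 to 237 ± 59.1 TPM. Epithelial junction genes gave 7 rises and 2 falls among 24 members, and 15 did not pass (8 and 3 over the list alone), with camera adjusted p = 0.110. The claudin gene CLDN4 rose from 11.99 ± 0.186 to 109 ± 29.04 TPM.

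In the BMP response list, 8 of 11 rose, 0 fell and 3 did not pass (8 and 0 over the list alone), with camera adjusted p = 2.99e-05, or 0.455 with an estimated correlation. MSX2, a homeobox gene induced by BMP, rose from 0.496 ± 0.111 to 62.7 ± 4.98 TPM, and ID2, an inhibitor of differentiation, from 10.1 ± 5.18 to 276 ± 37.2 TPM. Retinoic acid response genes gave 9 rises and 0 falls among 11 members, and 2 did not pass (10 and 0 over the list alone), with camera adjusted p = 9.09e-06, or 0.438 with an estimated correlation. The HOX paralogs 1 to 4 list had 9 rises and 0 falls among 12 members, and 3 did not pass (10 and 0 over the list alone), with camera adjusted p = 2.28e-06, or 0.455 with an estimated correlation. HOXA1 reached 478 ± 53.04 TPM, HOXB2 70.9 ± 15.4 TPM and HOXB1 69.6 ± 13.8 TPM. MEIS2, which encodes a partner of HOX proteins on DNA, rose from 0.608 ± 0.649 to 245 ± 46.7 TPM, and PCAT14, a long non-coding RNA, from 6.63 ± 2.95 to 1286 ± 304 TPM. WNT response genes gave 9 rises and 0 falls among 14 members, and 5 did not pass (9 and 0 over the list alone), with camera adjusted p = 1.24e-04, or 0.475 with an estimated correlation. RNF43, a ubiquitin ligase that removes WNT receptors, rose from 0.485 ± 0.126 to 22.0 ± 2.41 TPM, while SFRP1, which encodes a secreted WNT antagonist, fell from 132 ± 17.8 to 4.52 ± 0.698 TPM. In the NODAL pathway list, 1 of 7 rose, 3 fell and 3 did not pass (3 and 3 over the list alone), with camera adjusted p = 0.493. LEFTY1 fell to 6.67 ± 3.09 TPM, and CER1, an antagonist of NODAL and BMP, from 33.3 ± 15.4 to 0.0419 ± 0.0592 TPM. FGF and ERK response genes gave 2 rises and 7 falls among 12 members, and 3 did not pass (2 and 7 over the list alone), with camera adjusted p = 7.56e-04, or 0.581 with an estimated correlation. SPRY4, a feedback inhibitor of ERK signalling, fell from 84.5 ± 3.01 to 10.3 ± 3.88 TPM, and FOSL1, a subunit of AP-1, was higher (8.20 ± 0.356 and 29.6 ± 4.26 TPM). For YAP and TEAD response genes, 1 of 13 rose, 4 fell and 8 did not pass (1 and 4 over the list alone), with camera adjusted p = 0.0306, or 0.752 with an estimated correlation. The call ended without day 3 replicate 1 (0.170) and with a minimum of 5 TPM (0.0798). CCN1, a matricellular target of YAP, fell from 245 ± 47.6 to 35.8 ± 7.90 TPM.

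Of the p53 targets, 14 of 15 rose, 1 fell and 0 did not pass (14 and 1 over the list alone), with camera adjusted p = 2.23e-06, or 0.475 with an estimated correlation. CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 14.1 ± 1.70 to 97.9 ± 22.5 TPM by 2.70 (SE 0.25, limma adjusted p = 8.39e-05). FDXR rose from 11.6 ± 0.853 to 67.5 ± 8.24 TPM and ZMAT3 from 3.12 ± 0.494 to 19.6 ± 5.75 TPM, while TP53I3 fell from 39.4 ± 1.60 to 26.9 ± 0.137 TPM. The TP53I3 call ended without day 0 replicate 1 (limma adjusted p = 0.149) or day 0 replicate 2 (0.104) and with only the 2 days compared (0.0721). Cholesterol synthesis genes gave 0 rises and 18 falls among 20 members, and 2 did not pass (0 and 18 over the list alone), with camera adjusted p = 3.03e-13, or 0.438 with an estimated correlation. SC5D and SREBF2 were the members that did not pass. Core pluripotency genes gave 1 rise and 11 falls among 20 members, and 8 did not pass (1 and 11 over the list alone), with camera adjusted p = 9.65e-05, or 0.475 with an estimated correlation. FOXD3, a forkhead factor of pluripotent cells, fell from 14.2 ± 0.219 to 0.197 ± 0.0202 TPM, and LIN28A, an RNA-binding protein gene, rose from 855 ± 20.9 to 1361 ± 264 TPM (limma adjusted p = 0.0358). LIN28A did not pass with median-ratio scaling (0.0534), no filter (0.131), no trend (0.0609) or only the 2 days compared (0.0515). Nor did it pass without day 0 replicate 1 (0.133) or 2 (0.167), day 1 replicate 1 (0.0618) or 2 (0.0619), or day 3 replicate 2 (0.159). Primed pluripotency genes gave 1 rise and 10 falls among 12 members, and 1 did not pass (1 and 10 over the list alone), with camera adjusted p = 5.53e-06, or 0.455 with an estimated correlation. DUSP6, an ERK phosphatase, fell from 144 ± 9.95 to 7.48 ± 6.92 TPM and ZIC3, a zinc finger factor, rose from 52.8 ± 2.47 to 251 ± 49.2 TPM. In the naive pluripotency list, 5 of 7 rose, 1 fell and 1 did not pass (5 and 1 over the list alone), with camera adjusted p = 0.116. TBX3, a T-box factor, rose from 0.06995 ± 0.0372 to 10.2 ± 5.36 TPM. Endoplasmic reticulum and amino acid stress genes gave 1 rise and 7 falls among 16 members, and 8 did not pass (1 and 8 over the list alone), with camera adjusted p = 0.00650, or 0.581 with an estimated correlation. TRIB3, a pseudokinase of the stress response, fell from 18.1 ± 0.509 to 1.49 ± 0.406 TPM, while DDIT4, an inhibitor of mTORC1, rose from 19.2 ± 2.02 to 84.3 ± 8.45 TPM. The mitosis list had 2 rises and 0 falls among 16 members, and 14 did not pass (2 and 0 over the list alone), with camera adjusted p = 0.919. DNA replication genes gave 1 rise and 5 falls among 14 members, and 8 did not pass (1 and 8 over the list alone), with camera adjusted p = 0.0319, or 0.701 with an estimated correlation. The call ended without day 0 replicate 1 (0.0506) or day 3 replicate 1 (0.0881), and with median-ratio scaling 0 members rose and 8 fell. Antigen presentation and interferon genes gave 8 rises and 0 falls among 15 members, and 7 did not pass (8 and 0 over the list alone), with camera adjusted p = 0.0409, or 0.651 with an estimated correlation. That call ended with median-ratio scaling (0.0554), no trend (0.0532) and a minimum of 5 TPM (0.0953) and without day 0 replicate 2 (0.0812) or day 3 replicate 1 (0.346). On day 3 the median, the mean and the direction of the camera test differed in sign for the syncytiotrophoblast, extravillous trophoblast, primitive streak, NODAL pathway, mitosis and imprinted lists, none of which passed.

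Between day 0 and day 3, limma called 5388 of 16888 genes, 3210 higher and 2178 lower. With median-ratio scaling 3127 were higher and 3000 lower, without day 3 replicate 1 4637 and 2115, and without day 3 replicate 2 2309 and 2490, so the balance between rises and falls depends on the scaling and on the library. Without day 0 replicate 1 the count was 2874 and without day 0 replicate 2 it was 2561, where the remaining day 0 library is assumed to vary like the other days. Of 164 called results of named genes and list members, 38 ended when some library was left out. H2BC11, a histone H2B gene, fell from 38.1 ± 1.36 to 0.427 ± 0.287 TPM, in poly(A) libraries that hold only the polyadenylated part of histone mRNA. In GRCh38 coordinates of GENCODE release 29, TFAP2A lies on chromosome 6 from 10393186 to 10419659 on the minus strand, MEIS2 on chromosome 15 from 36889204 to 37101299 on the minus strand, MYC on chromosome 8 from 127735434 to 127741434 on the plus strand, CER1 on chromosome 9 from 14719724 to 14722717 on the minus strand and SFRP1 on chromosome 8 from 41261958 to 41309497 on the minus strand.

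By day 5, 17 of 20 core pluripotency genes had fallen, and 16 of 19 trophectoderm genes and all tested amnion and HOX genes had risen. Tested were 11 of 12 amnion members, 12 of 12 HOX members of paralogs 1 to 4 and 8 of 27 of paralogs 5 to 13. POU5F1 fell from 2385 TPM ± 24.6 (SD, n = 2) to 185 TPM ± 36.6 (SD, n = 2), and SOX2 from 111 TPM ± 1.84 (SD, n = 2) to 6.004 TPM ± 0.622 (SD, n = 2). KRT7, a keratin of simple epithelia and trophoblast, rose from 12.8 TPM ± 1.17 (SD, n = 2) to 1343 TPM ± 146 (SD, n = 2). The imprinted non-coding RNA H19 rose from 1.36 TPM ± 0.296 (SD, n = 2) to 3122 TPM ± 895 (SD, n = 2), and its neighbour IGF2, an insulin-like growth factor gene, from 0.285 TPM ± 0.0991 (SD, n = 2) to 675 TPM ± 21.2 (SD, n = 2). A non-coding gene without a symbol lies within IGF2 on the same strand and stood at 537 TPM ± 227 (SD, n = 2) on day 5. How reads were divided between these 2 genes is uncertain. Most genes of the mitosis, DNA replication and cholesterol synthesis lists were lower.

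In the core pluripotency list, 0 of 20 rose, 17 fell and 3 did not pass (0 and 17 over the list alone), with camera adjusted p = 1.35e-10, or 0.438 with an estimated correlation. TDGF1, a coreceptor of NODAL, fell from 647 ± 21.6 to 4.84 ± 1.18 TPM, a log2 difference of -6.81 (SE 0.16, limma adjusted p = 4.37e-08). USP44, a deubiquitinase, fell from 110.3 ± 5.53 to 1.07 ± 0.353 TPM, PRDM14 from 48.4 ± 0.497 to 0.224 ± 0.120 TPM and NANOG from 50.8 ± 1.78 to 10.04 ± 3.46 TPM. SALL4, LIN28A and LIN28B did not pass, and LIN28A stood at 772 ± 214 TPM. Primed pluripotency genes gave 0 rises and 10 falls among 12 members, and 2 did not pass (0 and 10 over the list alone), with camera adjusted p = 8.08e-07, or 0.455 with an estimated correlation. SFRP2, a secreted WNT antagonist, fell from 323 ± 25.9 to 3.92 ± 1.02 TPM. Naive pluripotency genes gave 5 rises and 2 falls among 7 members, and 0 did not pass (5 and 2 over the list alone), with camera adjusted p = 0.0829. The risers included TBX3, at 166 ± 31.5 TPM, and KLF4, at 27.6 ± 2.73 TPM from 1.76 ± 0.447, both of which other tissues also express. PDZD4 fell by 6.27 and HCN1 by 8.45. FOXD3-AS1, antisense to FOXD3, fell by 6.63, and reads of overlapping genes make its level uncertain.

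For the trophectoderm list, 16 of 19 rose, 1 fell and 2 did not pass (17 and 1 over the list alone), with camera adjusted p = 4.00e-09, or 0.438 with an estimated correlation. TFAP2A reached 274 ± 32.2 TPM by 8.08 (SE 0.24, limma adjusted p = 7.02e-08). GATA3 reached 139 ± 22.7 TPM, GATA2 47.4 ± 3.27 TPM, TFAP2C 135 ± 19.4 TPM and CDX2 31.6 ± 7.16 TPM. HAND1 reached 95.0 ± 18.0 TPM and NR2F2, a nuclear receptor gene, 52.7 ± 13.3 TPM. The keratins KRT8 and KRT18, partners in simple epithelia, rose to 1695 ± 93.4 and 1745 ± 349 TPM from 297 ± 7.46 and 502 ± 17.9. TEAD4 was lower, at 27.2 ± 4.54 TPM, and DAB2 (4.67 ± 1.15 and 11.8 ± 8.16 TPM) and PLAC8 (0.973 ± 0.842 and 1.63 ± 0.0994 TPM) did not pass. Cytotrophoblast genes gave 9 rises and 2 falls among 11 members, and 0 did not pass (9 and 2 over the list alone), with camera adjusted p = 0.00667, or 0.583 with an estimated correlation. The risers ELF5, TP63, VGLL1 and XAGE2 reached 1 TPM only on day 5, so the expression filter admitted them through their rise. Their part in the count and in the list call was thus nearly fixed in advance. VGLL1, a TEAD cofactor of trophoblast, was listed at 0 TPM in both day 0 libraries and at 32.6 ± 5.66 TPM on day 5. ELF5, an ETS factor of trophoblast progenitors, rose from 0.0429 ± 0.0606 to 7.08 ± 0.672 TPM and TP63 from 0.0279 ± 0.0270 to 3.46 ± 0.273 TPM, while the integrin gene ITGA6 fell from 82.6 ± 0.899 to 19.6 ± 4.16 TPM. In the syncytiotrophoblast list, 3 of 7 rose, 3 fell and 1 did not pass (3 and 3 over the list alone), with camera adjusted p = 0.806. Of its 28 members 22 were in the table, and most of these stayed under the expression filter. CYP11A1, the enzyme that starts steroid synthesis, rose from 0.892 ± 0.554 to 19.1 ± 0.654 TPM and TFPI2 fell from 12.8 ± 2.18 to 0.916 ± 0.0525 TPM. CGA, the alpha subunit of chorionic gonadotropin, stayed under the filter at 0.935 and 1.51 TPM in the day 5 libraries. Extravillous trophoblast genes gave 4 rises and 4 falls among 8 members, and 0 did not pass (4 and 4 over the list alone), with camera adjusted p = 0.786. These 8 were the tested part of 14 members. DIO2 rose from 0.997 ± 0.181 to 12.9 ± 7.89 TPM and FLT1, a receptor of VEGF, fell from 58.6 ± 1.23 to 0.904 ± 0.351 TPM.

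Every tested amnion gene rose on day 5: 11 of 11 rose, 0 fell and 0 did not pass (11 and 0 over the list alone), with camera adjusted p = 2.43e-07, or 0.438 with an estimated correlation. Of these, VTCN1, TFAP2B, WNT6 and MUC16 reached 1 TPM only on day 5, so the expression filter admitted them through their rise, which was nearly fixed in advance. ISL1 stood at 0.877 and 1.77 TPM in the day 3 libraries, so it too met the filter of 2 libraries only through day 5. VTCN1 rose from 0.127 ± 0.0739 to 37.0 ± 18.6 TPM, ISL1, a homeobox gene, from 0.129 ± 0.0258 to 32.9 ± 0.0442 TPM, IGFBP3 from 9.06 ± 2.24 to 331 ± 4.40 TPM and HEY1, a NOTCH target, from 1.53 ± 0.0161 to 83.7 ± 8.78 TPM. Surface ectoderm and epidermis genes gave 5 rises and 2 falls among 8 members, and 1 did not pass (5 and 2 over the list alone), with camera adjusted p = 0.0911. Paraxial and lateral mesoderm genes gave 6 rises and 2 falls among 10 members, and 2 did not pass (7 and 2 over the list alone), with camera adjusted p = 0.0758. HAND2 was listed at 0 TPM in both day 0 libraries and at 11.7 ± 0.634 TPM on day 5, and KDR, a receptor of VEGF, fell from 21.8 ± 2.53 to 0.885 ± 0.656 TPM. The primitive streak list had 0 rises and 2 falls among 5 members, and 3 did not pass (0 and 1 over the list alone), with camera adjusted p = 0.617. In the endoderm list, 5 of 10 rose, 4 fell and 1 did not pass (5 and 4 over the list alone), with camera adjusted p = 0.886. GATA6 rose from 0.0329 ± 0.0132 to 20.6 ± 1.25 TPM, AFP went from 41.1 ± 3.72 TPM to 0 TPM in both libraries, and SOX17 stayed under the filter, at 0 TPM in both day 5 libraries. Neural progenitor genes gave 3 rises and 3 falls among 6 members, and 0 did not pass (3 and 3 over the list alone), with camera adjusted p = 0.831. These 6 were the tested part of 14 members. IRX3 rose from 0.567 ± 0.183 to 132 ± 4.09 TPM, while SOX3 fell from 23.7 ± 0.752 to 10.4 ± 3.75 TPM. PAX6 rose from 0.565 ± 0.361 to 3.37 ± 2.61 TPM (limma adjusted p = 0.0196), but not without day 0 replicate 1 (0.112) or day 5 replicate 1 (0.145), with no filter (0.0909), with only the 2 days compared (0.0539) or with a pseudocount of 0.1 TPM (0.0713). Neuron genes gave 0 rises and 4 falls among 8 members, and 4 did not pass (0 and 4 over the list alone), with camera adjusted p = 0.0738. The tubulin gene TUBB3 fell from 185 ± 13.4 to 11.7 ± 7.80 TPM. For neural crest genes, 6 of 11 rose, 4 fell and 1 did not pass (6 and 4 over the list alone), with camera adjusted p = 0.650. MSX1 rose from 0.130 ± 0.184 to 131 ± 31.2 TPM and ETS1 fell from 32.3 ± 2.72 to 0.651 ± 0.206 TPM. Cardiac and endothelial genes gave 3 rises and 3 falls among 7 members, and 1 did not pass (3 and 3 over the list alone), with camera adjusted p = 0.971. CDH5, the endothelial cadherin, rose from 0.335 ± 0.104 to 17.4 ± 5.44 TPM. TIE1, an endothelial receptor gene, fell from 10.3 ± 2.77 to 0.473 ± 0.0588 TPM and TNNT2, a troponin gene, from 20.0 ± 5.76 to 3.04 ± 1.30 TPM.

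Epithelial junction genes gave 14 rises and 1 fall among 24 members, and 9 did not pass (14 and 1 over the list alone), with camera adjusted p = 0.00199, or 0.719 with an estimated correlation. DSP, the desmosome protein desmoplakin, rose from 20.0 ± 1.10 to 443 ± 40.2 TPM and CDH1 from 127 ± 0.259 to 473 ± 31.2 TPM. The mesenchymal list had 1 rise and 4 falls among 11 members, and 6 did not pass (1 and 5 over the list alone), with camera adjusted p = 0.0829. CDH2, the neural cadherin, fell from 90.6 ± 10.4 to 5.22 ± 2.11 TPM, VIM, the filament protein vimentin, from 235 ± 50.6 to 53.02 ± 21.8 TPM and TAGLN from 889 ± 113 to 31.6 ± 2.87 TPM. Basement membrane genes gave 6 rises and 4 falls among 13 members, and 3 did not pass (6 and 4 over the list alone), with camera adjusted p = 0.342. The laminin gene LAMB1 rose from 35.7 ± 1.39 to 431 ± 111 TPM and NID1 fell from 21.0 ± 0.458 to 1.83 ± 0.777 TPM. In the retinoic acid response list, 9 of 11 rose, 0 fell and 2 did not pass (9 and 0 over the list alone), with camera adjusted p = 7.05e-05, or 0.438 with an estimated correlation. CRABP2 reached 2752 ± 345 TPM. All tested HOX genes rose: for paralogs 1 to 4, 12 of 12 rose, 0 fell and 0 did not pass (12 and 0 over the list alone), with camera adjusted p = 7.26e-07, or 0.455 with an estimated correlation, and for paralogs 5 to 13, 8 of 8 rose, 0 fell and 0 did not pass (8 and 0 over the list alone), with camera adjusted p = 3.57e-05, or 0.455 with an estimated correlation. Of the 27 members of paralogs 5 to 13, 23 were in the table and 8 were tested, so most stayed under the expression filter. In any list, a gene that reached this filter only on day 5, such as HOXB4, HAND2 or GATA6, could hardly do other than rise. HOXA5 was listed at 0 TPM in both day 0 libraries and at 45.0 ± 3.32 TPM on day 5, and HOXB6 went from 0 in both to 18.9 ± 6.49 TPM. BMP response genes gave 8 rises and 0 falls among 11 members, and 3 did not pass (8 and 0 over the list alone), with camera adjusted p = 2.53e-04, or 0.457 with an estimated correlation. MSX2 reached 203 ± 45.7 TPM. WNT response genes gave 8 rises and 1 fall among 14 members, and 5 did not pass (8 and 1 over the list alone), with camera adjusted p = 0.0402, or 0.719 with an estimated correlation. That call ended with median-ratio scaling (0.0615), only the 2 days compared (0.0836) and mitochondrial and ribosomal protein genes left out (0.0588) and without day 3 replicate 1 (0.0945), day 3 replicate 2 (0.0907) or day 5 replicate 1 (0.0741). NODAL pathway genes gave 1 rise and 5 falls among 7 members, and 1 did not pass (1 and 5 over the list alone), with camera adjusted p = 0.0622. FGF and ERK response genes had 0 rises and 8 falls among 12 members, and 4 did not pass (1 and 9 over the list alone), with camera adjusted p = 7.11e-04, or 0.581 with an estimated correlation. YAP and TEAD response genes gave 2 rises and 5 falls among 13 members, and 6 did not pass (2 and 5 over the list alone), with camera adjusted p = 0.148. CCN2 fell from 258 ± 50.1 to 8.93 ± 2.91 TPM.

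In the mitosis list, 0 of 16 rose, 14 fell and 2 did not pass (0 and 14 over the list alone), with camera adjusted p = 1.10e-05, or 0.475 with an estimated correlation. CCNA2, a cyclin of S and G2 phase, fell from 109 ± 1.24 to 34.5 ± 4.45 TPM and PLK1, a mitotic kinase, from 130.3 ± 6.93 to 50.5 ± 11.7 TPM, while TOP2A (134 ± 1.86 and 116 ± 7.61 TPM) and CENPF (71.6 ± 1.67 and 71.1 ± 22.8 TPM) did not pass. DNA replication genes gave 0 rises and 13 falls among 14 members, and 1 did not pass (0 and 13 over the list alone), with camera adjusted p = 8.25e-06, or 0.455 with an estimated correlation. RRM2, a subunit of ribonucleotide reductase, fell from 244 ± 17.7 to 51.0 ± 2.01 TPM. All cholesterol synthesis genes tested were lower: 0 of 20 rose, 20 fell and 0 did not pass (0 and 20 over the list alone), with camera adjusted p = 3.55e-13, or 0.438 with an estimated correlation. PCSK9, which lowers the LDL receptor, fell from 100.2 ± 6.46 to 1.79 ± 0.125 TPM. The p53 targets gave 2 rises and 5 falls among 15 members, and 8 did not pass (2 and 5 over the list alone), with camera adjusted p = 0.0686. Glycolysis and hypoxia genes gave 4 rises and 7 falls among 19 members, and 8 did not pass (4 and 7 over the list alone), with camera adjusted p = 0.522. The peptide hormone gene ADM fell from 150.0 ± 13.8 to 9.34 ± 0.701 TPM. Endoplasmic reticulum and amino acid stress genes had 4 rises and 9 falls among 16 members, and 3 did not pass (4 and 10 over the list alone), with camera adjusted p = 0.0347, or 0.701 with an estimated correlation. That call ended with median-ratio scaling (0.0554) and a minimum of 5 TPM (0.0608). PSAT1, an enzyme of serine synthesis, fell from 349 ± 8.57 to 46.6 ± 1.39 TPM and HERPUD1 rose from 40.7 ± 5.92 to 289 ± 48.6 TPM. Antigen presentation and interferon genes had 4 rises and 4 falls among 15 members, and 7 did not pass (4 and 4 over the list alone), with camera adjusted p = 0.613. DNA methylation genes gave 1 rise and 1 fall among 6 members, and 4 did not pass (1 and 1 over the list alone), with camera adjusted p = 0.836, and 3 fell with median-ratio scaling. TET2 rose from 0.632 ± 0.100 to 5.13 ± 0.884 TPM. Of the imprinted genes, 5 of 9 rose, 3 fell and 1 did not pass (5 and 3 over the list alone), with camera adjusted p = 0.485. GRB10, an adaptor of growth factor receptors, fell from 57.8 ± 1.05 to 5.10 ± 1.65 TPM. The ribosomal protein list had 19 rises and 0 falls among 24 members, and 5 did not pass (22 and 0 over the list alone), with camera adjusted p = 1.30e-04, or 0.738 with an estimated correlation, in libraries where these genes took 22.9% and 20.5% of TPM against 13.8% and 13.9% on day 0. With median-ratio scaling, 9 ribosomal protein genes rose and 0 fell. Mitochondrially encoded genes gave 0 rises and 1 fall among 13 members, and 12 did not pass (0 and 0 over the list alone), with camera adjusted p = 0.348, in libraries where they took 6.32% and 12.1% of TPM. The called member, MT-ATP8 (limma adjusted p = 0.0367), did not pass with median-ratio scaling (0.204), no filter (0.218) or only the 2 days compared (0.0657), or without day 0 replicate 1 (0.165), day 0 replicate 2 (0.129), day 1 replicate 1 (0.0615), day 1 replicate 2 (0.0607) or day 5 replicate 1 (0.224). On day 5 the median, the mean and the direction of the camera test differed in sign for the extravillous trophoblast, endoderm, cardiac and endothelial, glycolysis and hypoxia, and DNA methylation lists, none of which passed.

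**Figure D3:**
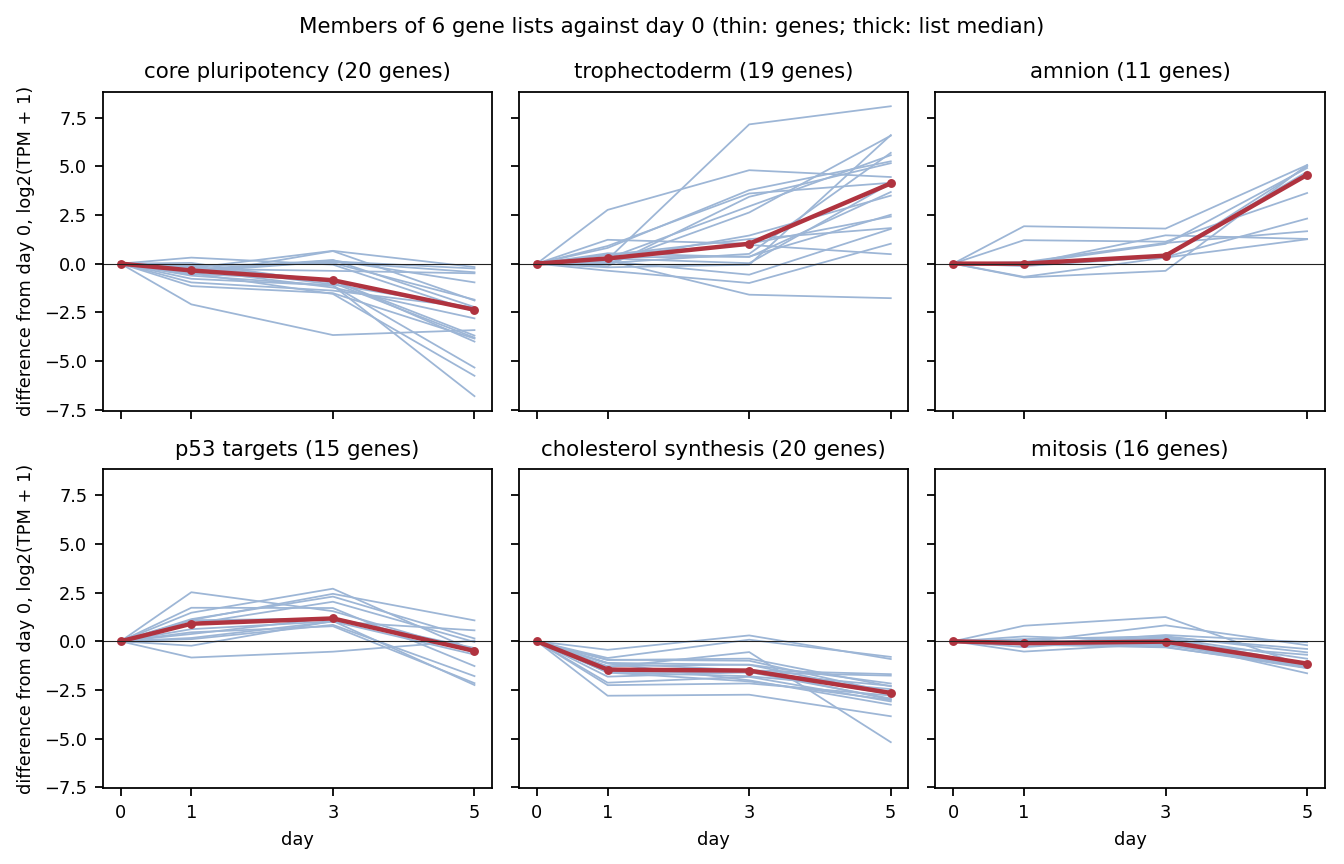
Differences from day 0 on the log2(TPM + 1) scale against day for the tested members of 6 gene lists, where thin lines are genes and the thick line is the list median. The median of the core pluripotency list fell by 2.37 on day 5, that of the amnion list rose by 4.56, and that of the p53 targets was 1.17 on day 3 and -0.49 on day 5.

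Between day 0 and day 5, limma called 8916 genes of 16888, 4715 higher and 4201 lower, and 4983 of them by at least 1 on the log2 scale. Without day 5 replicate 1, 3793 were higher and 3799 lower, and with mitochondrial and ribosomal protein genes left out, which moved the median of all genes to 0.18, 5913 were higher and 3972 lower. TMSB4XP6, a processed pseudogene that shares reads with TMSB4X, went from 74.8 ± 11.1 TPM to 0 TPM in both day 5 libraries. Its values moved in steps with those of TMSB4XP8 (76.117 TPM for both in day 1 replicate 1), so its level too may rest on very few reads. Its call ended without either day 5 library and with no filter (limma adjusted p = 0.0668). Of 197 called results of named genes and list members, 20 ended when some library was left out. In GRCh38 coordinates of GENCODE release 29, H19 lies on chromosome 11 from 1995176 to 2001470 on the minus strand, IGF2 on chromosome 11 from 2129112 to 2149603 on the minus strand, TDGF1 on chromosome 3 from 46574534 to 46582463 on the plus strand, KRT7 on chromosome 12 from 52232520 to 52252186 on the plus strand and PDZD4 on chromosome X from 153802166 to 153830565 on the minus strand.

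From day 1 to day 3, TFAP2A and DLX5 rose and LEFTY1 and SERPINE1 fell. TFAP2A rose from 0.190 TPM ± 0.268 (SD, n = 2) to 146 TPM ± 39.5 (SD, n = 2) and DLX5 from 0.273 TPM ± 0.0912 (SD, n = 2) to 114 TPM ± 33.9 (SD, n = 2). LEFTY1 fell from 301 TPM ± 36.8 (SD, n = 2) to 6.67 TPM ± 3.09 (SD, n = 2). SERPINE1, an inhibitor of plasminogen activation, fell from 235 TPM ± 29.9 (SD, n = 2) to 5.99 TPM ± 4.14 (SD, n = 2). In the trophectoderm list, 9 of 19 rose, 2 fell and 8 did not pass (9 and 2 over the list alone). Of the surface ectoderm and epidermis list, 3 of 8 rose, 1 fell and 4 did not pass (3 and 2 over the list alone). GATA2 rose from 0.232 ± 0.0624 to 14.1 ± 5.28 TPM. For BMP response genes, 8 of 11 rose, 0 fell and 3 did not pass (8 and 1 over the list alone). MSX2 rose by 5.05 (SE 0.21, limma adjusted p = 5.37e-06). In the NODAL pathway, 3 of 7 rose, 4 fell and 0 did not pass (3 and 4 over the list alone). NODAL fell from 188 ± 32.9 to 22.9 ± 2.86 TPM. FGF and ERK response genes gave 0 rises and 8 falls among 12 members, and 4 did not pass (0 and 8 over the list alone). Of the p53 targets, 8 of 15 rose, 1 fell and 6 did not pass (9 and 1 over the list alone). FDXR rose from 25.8 ± 1.24 to 67.5 ± 8.24 TPM while GDF15 fell from 38.1 ± 4.19 to 19.1 ± 4.17 TPM. The GDF15 call ended without day 1 replicate 1 (0.174), day 1 replicate 2 (0.102) or day 3 replicate 1 (0.0987), and with no filter (0.106). Cholesterol synthesis genes gave 3 rises and 1 fall among 20 members, and 16 did not pass (3 and 1 over the list alone). HOX paralogs 1 to 4 gave 8 rises and 0 falls among 12 members, and 4 did not pass (9 and 0 over the list alone). GRHL3 and MEIS2 were among the largest rises (5.37 and 4.61), and NPPB, a natriuretic peptide gene, and ANXA1, an annexin gene, among the largest falls (-4.73 and -4.12). RNVU1-4, a small nuclear RNA gene that poly(A) selection captures poorly, fell to 0 TPM in both day 3 libraries, and its call ended without day 1 replicate 2 (0.0800) or day 3 replicate 2 (0.0722), and with no filter (0.0884). In limma, 3999 of 16888 genes passed, 2455 higher and 1544 lower. With median-ratio scaling 4721 passed, of which 2276 were higher and 2445 lower, and without day 3 replicate 2 1359 were higher and 1552 lower, so the balance between rises and falls depends on the scaling and on the library. Of 149 called results of named genes and list members, 61 ended when some library was left out. The count was 1360 without day 1 replicate 1 and 1367 without day 1 replicate 2, where the remaining day 1 library is assumed to vary like the other days, and 6270 without day 3 replicate 1 (4487 higher and 1783 lower). In GRCh38 coordinates of GENCODE release 29, DLX5 lies on chromosome 7 from 97020392 to 97024950 on the minus strand, MSX2 on chromosome 5 from 174724533 to 174730893 on the plus strand and LEFTY1 on chromosome 1 from 225886282 to 225911382 on the minus strand.

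From day 3 to day 5, H19, KRT23, KRT7 and 10 of 11 amnion genes rose, and most core pluripotency genes, p53 targets and mitosis genes fell. H19 rose from 7.30 TPM ± 6.73 (SD, n = 2) to 3122 TPM ± 895 (SD, n = 2) and KRT23, a type I keratin, from 0.603 TPM ± 0.0639 (SD, n = 2) to 227 TPM ± 50.2 (SD, n = 2). SMOC1, a secreted calcium-binding protein gene, rose from 0.216 TPM ± 0.137 (SD, n = 2) to 129.8 TPM ± 25.1 (SD, n = 2). PMAIP1, a pro-apoptotic BH3 gene that p53 activates, fell from 91.9 TPM ± 0.7999 (SD, n = 2) to 1.84 TPM ± 0.357 (SD, n = 2). Unlike most p53 targets it had not risen by day 3, from 109.9 TPM ± 0.0799 (SD, n = 2) on day 0 (limma adjusted p = 0.233). Of the p53 targets, 1 of 15 rose, 13 fell and 1 did not pass (1 and 14 over the list alone). RRM2B, a p53-induced ribonucleotide reductase subunit, fell by 3.29 (SE 0.23, limma adjusted p = 1.12e-05), and CDKN1A fell from 97.9 ± 22.5 to 10.02 ± 3.95 TPM. In the core pluripotency list, 0 of 20 rose, 16 fell and 4 did not pass (0 and 17 over the list alone). SOX2 fell from 62.2 ± 7.79 to 6.004 ± 0.622 TPM. Trophectoderm genes gave 15 rises and 0 falls among 19 members, and 4 did not pass (16 and 0 over the list alone), with KRT7 at 13.7 ± 8.80 TPM on day 3 and 1343 ± 146 TPM on day 5. The amnion list had 10 rises and 0 falls among 11 members, and 1 did not pass (10 and 0 over the list alone). HEY1 rose from 0.961 ± 0.228 to 83.7 ± 8.78 TPM. Mitosis genes gave 0 rises and 14 falls among 16 members, and 2 did not pass (0 and 15 over the list alone). BUB1, a checkpoint kinase, fell from 236 ± 49.7 to 39.3 ± 8.68 TPM. Cholesterol synthesis genes gave 0 rises and 18 falls among 20 members, and 2 did not pass (0 and 18 over the list alone). WNT response genes gave 4 rises and 4 falls among 14 members, and 6 did not pass (4 and 5 over the list alone). TCF7 fell from 74.2 ± 8.57 to 13.4 ± 1.72 TPM. LINC00678, a long non-coding RNA, fell from 341 ± 5.23 to 10.8 ± 7.17 TPM. In limma, 6460 of 16888 genes passed, 2869 higher and 3591 lower, and 4181 passed without day 5 replicate 2, where the remaining day 5 library is assumed to vary like the other days. With median-ratio scaling 7243 passed, 3756 higher and 3487 lower, and rises also outnumbered falls without day 3 replicate 2 (3471 and 2950) and with mitochondrial and ribosomal protein genes left out (3879 and 3360). Of 169 called results of named genes and list members, 32 ended when some library was left out. In GRCh38 coordinates of GENCODE release 29, KRT23 lies on chromosome 17 from 40922696 to 40937634 on the minus strand, SMOC1 on chromosome 14 from 69854131 to 70032366 on the plus strand and PMAIP1 on chromosome 18 from 59899948 to 59904306 on the plus strand.

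Over the whole course, 10564 of 16888 genes (62.6%) differed among the 4 days in limma's F test over the contrasts against day 0. POU5F1 (adjusted p = 7.44e-07), CDX2 (2.68e-05), HMGCS1 (4.78e-06) and CDKN1A (2.46e-05) were among them.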

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

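Leaving out short non-coding genes, or mitochondrial and ribosomal protein genes, was chosen after seeing the data; the other alternatives were planned. No called result of a named gene or list reversed its direction in any alternative, and a difference called in neither of 2 fits counted as kept. FN1 and MT-CYB, not called for day 5 against day 0, were called when either day 5 library was left out, in opposite directions (FN1 0.54 without replicate 1 and -0.95 without replicate 2, MT-CYB 0.51 and -0.47). Of 1894 results of named genes and list members, 754 were called, and 557 of these stayed called in every alternative run. The calls lost numbered 138 with no filter, 73 with only the 2 days compared, 27 with no trend and 25 with a pseudocount of 0.1 TPM. A replicate block lost 24 calls and added 15, and median-ratio scaling lost 17 and added 91. Leaving out 1 library lost 32 to 124 and added 1 to 198. Of 47 list calls, 37 stayed called in all alternatives but the estimated correlation. With that correlation camera in limma called 0 of 114, and its smallest adjusted p was 0.438. It had 12 at an unadjusted p below 0.05, against 55 with the preset correlation. It rests on 4 residual degrees of freedom and has little power, so it cannot decide whether the 47 calls hold. With no filter, which tests 31129 genes, 531 genes were called for day 1 against day 0 and 2448 for day 3 against day 1. With median-ratio scaling, 1564 were called for day 1 against day 0. With only the 2 days compared, and so fewer samples, counts were 2536 for day 1 against day 0 (1236 higher and 1300 lower), 1988 for day 3 against day 1 and 3967 for day 5 against day 3. The main fit shares 1 spread per gene over all days. Over genes, the SD of the difference between replicates was 0.361 on day 0 and 0.353 on day 1. It was 0.461 on day 3 and 0.450 on day 5, and the main fit does not allow for such a difference between days. The cause of the moved counts was not tested. When each library was left out in turn, counts ranged from 241 to 1810 for day 1 against day 0, 2561 to 6752 for day 3 against day 0, 6352 to 10122 for day 5 against day 0, 1360 to 6270 for day 3 against day 1, 4181 to 7109 for day 5 against day 3, 8395 to 12290 for any day and 44 to 50 for list tests. Genes removed by the minimum of 5 TPM or by a left-out set have no value there, and of the 680 gene calls that the minimum kept, 0 were lost. All other counts of genes called in a comparison or on any day, and of list tests called, lay within 1.5 times the reported value, while counts of called members of single lists could move further (ribosomal protein rises on day 5 from 19 to 9 with median-ratio scaling). Genes called under both scalings numbered 1004 of 1018 for day 1, 5127 of 5388 for day 3 and 8719 of 8916 for day 5 against day 0. Replicates share only a number: deviations from the day means correlated between days at -0.0766 to 0.0636, and with a replicate block 858, 5090 and 8680 genes were called for days 1, 3 and 5 against day 0, 3625 and 6142 for the later steps, 10119 for any day and 47 list tests. Depth is unknown, so what it limits cannot be stated.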

Other observations

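The tests of RNA from day 3 cells, of RNA from day 5 cells, of exposure to retinoic acid and of slower division were chosen only after the results were seen; the genes in the next paragraph were also chosen after their values were seen.

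The core histone gene H2BC12, in poly(A) libraries that hold only the polyadenylated part of histone mRNA, fell from 117 TPM ± 0.394 (SD, n = 2) on day 0 to 4.54 TPM ± 0.0110 (SD, n = 2) on day 5 (limma adjusted p = 1.01e-07) and H2AC6 from 76.8 ± 5.59 to 2.94 ± 1.44 TPM (1.23e-06). H1-0, a linker histone of differentiated cells, rose from 20.5 ± 0.817 to 288 ± 38.3 TPM (1.66e-07), and H1-10 from 59.2 ± 2.98 to 129.9 ± 3.69 TPM (7.17e-05). MEIS1, which encodes a partner of HOX proteins on DNA, rose from 0.816 ± 0.340 to 148 ± 12.3 TPM (4.06e-07), PBX1 from 63.1 ± 4.94 to 178 ± 45.1 TPM (4.75e-04) and PBX2 from 42.4 ± 1.65 to 143 ± 7.65 TPM (1.93e-05). Some genes were highest on day 3. HPGD, which degrades prostaglandins, stood at 5.21 ± 1.51, 34.2 ± 7.96, 331 ± 61.8 and 59.5 ± 26.7 TPM on days 0, 1, 3 and 5, and rose from day 1 to day 3 (1.91e-04) and fell from day 3 to day 5 (2.47e-04). APELA, a peptide ligand of the apelin receptor, stood at 88.9 ± 7.96, 144 ± 7.32, 462 ± 57.5 and 19.5 ± 5.02 TPM, and rose from day 1 to day 3 (4.22e-04) and fell from day 3 to day 5 (6.85e-07). HAS2, a hyaluronan synthase, was highest on day 1, at 168 ± 10.9 TPM against 11.7 ± 9.70 on day 0 (0.00175) and 36.9 ± 17.1 on day 3 (0.0107). The call between days 1 and 3 ended with no filter (0.0839) and without day 1 replicate 1 (0.0647), day 1 replicate 2 (0.0530) or day 3 replicate 1 (0.0595).

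Day 0 replicate 1 held transcripts that were high on day 1: HOXA1 stood at 13.2 TPM against 0 in replicate 2, HOTAIRM1 at 16.9 against 0.0839, CYP26A1 at 56.7 against 3.76 and CDX1 at 2.85 against 0. RNA from day 3 or day 5 cells in that library is argued against, since 8 genes called higher on day 3 by at least 4 log2 and under 1 TPM on day 1 had a median share of 0.0685% of their day 3 rise there (quartiles -0.0193% and 0.351%), and 44 genes called higher on day 5 by at least 5 log2 and under 1 TPM on day 1 had 0% of their day 5 rise (-0.0247% and 0.0779%). The bound on the rise leaves out genes raised in that library, so genes close to it could only show a share near 0. IGF2, HAPLN1 and TFAP2A lay far above it (675, 456 and 274 TPM on day 5) and had 0.0208%, -0.360% and 0.00895%. Of the genes called higher on day 1, 58 others rose by at least 2 log2 and reached 10 TPM, replicate 1 lay above replicate 2 in 56 of these, and the median excess was 7.09% of the day 1 rise (quartiles 5.03% and 9.42%), so RNA from day 1 cells may be in this library. The share was not even across them: SERPINB9, FOSL1 and ACTA1 had 0.305%, 1.79% and 2.10%. Genes that fell on day 1 were not examined for such a share. The retinoic acid response and HOX genes had a median share of 6.31% over 10 genes, and the WNT response and NODAL pathway genes had 4.34% over 11 genes (quartiles 3.96% and 5.87%), above the 1% set as the limit for exposure of some day 0 cells to retinoic acid alone, which counts against it only if retinoic acid alone leaves these genes unmoved, and no library tests that. The first set holds CYP26A1 (8.33%) and HOXA1 (7.87%), and the second CDX1 (4.68%), whose day 0 values had drawn attention to this library. A short exposure of day 0 cells to the whole differentiation medium was not tested.

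Of 15 p53 targets, 14 were called higher and 1 lower on day 3 against day 0, and 13 lower and 1 higher on day 5 against day 3. Scaling between libraries as the cause of the rise is argued against, as far as median ratios measure it. With that scaling the list median on day 3 was 1.07, against 1.17 as deposited, and 14 of 15 members stayed called higher. A change in total RNA per cell cannot be seen in TPM. A list of 23 other p53 targets, written before its values were seen, had 16 called higher on day 3 against day 0 and 1 lower (17 higher adjusted over the list alone), and 17 lower and 1 higher on day 5 against day 3. On day 1 against day 0 this second list had only 2 called higher and 0 lower (4 higher adjusted over the list alone). A rise and fall of p53 activity is a candidate explanation, although protein activity was not measured. For the rise of the second list on day 3, camera gave p = 6.21e-06 with the preset correlation and 0.160 with an estimated correlation. The test with an estimated correlation rests on 4 residual degrees of freedom and has little power, so the 0.160 decides nothing here. What would activate p53 was not tested.

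Of 20 cholesterol synthesis genes, 17 were called lower on day 1. As far as median ratios measure it, scaling between libraries is argued against. With that scaling the list median was -1.41, against -1.45 as deposited, and 19 of 20 members were called lower on day 1. TPM cannot show a change in total RNA per cell. Slower division is not excluded but has little support: on day 1 the mitosis and DNA replication lists had medians of -0.10 and -0.26 and 0 called falls (-0.05 and -0.22 with median-ratio scaling, with 0 and 1 falls), against -1.45 for cholesterol synthesis, and the camera call of DNA replication (adjusted p = 0.0308, or 0.701 with an estimated correlation) ended with that scaling (0.0608). More sterol in the cells was taken to predict a fall of fatty acid genes under SREBP control and a rise of genes that the sterol sensor LXR activates. Of 7 such fatty acid genes, 5 were called lower on day 1 in limma (7 adjusted over the list alone), with a median of -1.23. Of 8 LXR targets, 0 were called higher and 2 lower (3 adjusted over the list alone), with a median of -0.43. The LXR part of the prediction was thus not met. The explanation stays undecided, because no value here shows that more sterol would raise LXR targets in these cells. A change of lipid supply between days 0 and 1 was not tested.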
